A study of Mus musculus with 80 samples.

How the data were processed

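RNA of skeletal muscle was measured in 40 C57BL/6 mice, 20 female and 20 male, of 4 age classes. Total RNA of each mouse was made into 33P-labelled cDNA and hybridised to a pair of filters of spotted cDNA clones, mouse17K-A and mouse17K-B, so that 80 arrays hold 8448 clones each and 16896 clones per mouse. The authors deposited a score per spot (a z-score), standardised within each array to a mean of 0 and a standard deviation (SD) of 1 over its clones, with no missing values. The shape of the distribution, with a long low tail, is that of log intensities, but the log base and the steps before the score (image quantification, background, scaling) are not given in the sources used here. A difference is therefore in SDs of the array, written array SD below, and no fold change can be given. The number of arrays limits the precision, and the signal over background of a spot cannot be read from the scores.

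Clones were named by the symbols and gene identifiers that the platform tables pair with them. Of the 16896 clones, 9663 have 1 symbol, 436 several and 6797 none. Among the clones with 1 symbol, 9641 matched the mouse reference annotation (GRCm38.p6) by gene identifier and 22 did not. The named clones cover 7151 genes, 5293 with 1 clone and 1858 with several. For gene lists, and for the rule that chose the genes named in the text, a gene was represented by its clone with the highest mean percentile within its filter.

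The mice fall into 8 groups of 5 separate animals by sex and age class (17-44 d, 169-194 d, 476-499 d and 704-743 d). The class of 17-44 d holds 5 mice of 17-21 d (3 female, 2 male) and 5 of 33-44 d (2 female, 3 male). The comparisons, the gene lists, the rule for named genes and most of the other settings were fixed before the data were examined. There were 11 comparisons: 169-194 d against 17-44 d (called maturation here), 704-743 d against 169-194 d, 476-499 d against 169-194 d, 704-743 d against 476-499 d, the slope on age over all mice and over the 30 mice from 169 d, females against males over all classes and over the 3 older classes, the difference between the sexes in the age slope and in maturation, and 33-44 d against 17-21 d. Contrasts of classes weighted the sexes equally.

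Each clone was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided tests) within its filter, and p was adjusted by the Benjamini-Hochberg method over the clones of both filters, with a threshold of 0.05. Slopes are per 100 d. The rule named, for each direction, the 10 genes (5 in the smaller comparisons) with the most extreme moderated t among those past the threshold, and otherwise the 5 (or 3) with the smallest p, as not past it. Genes outside the rule are said to have been chosen after their values were seen.

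Of 29 lists of genes, 28 had at least 3 measured genes and were tested: extracellular matrix, imprinted growth genes, cell cycle, cytosolic ribosome, mitochondrial ribosome, oxidative phosphorylation, TCA cycle and fatty acid oxidation, glycolysis, proteasome, fast fibre, slow fibre, sarcomere and excitation-contraction, developmental muscle, denervation and atrophy, immune and antigen presentation, lysosome, adipocyte, erythroid and blood, nerve and Schwann cell, endothelial cell, skin and epithelium, heat shock and chaperones, antioxidant, circadian clock, p53 and senescence, insulin-like growth factor axis, X inactivation and escape, and hormone-responsive genes. The Y-linked list has 2 measured genes, given singly. Lists were compared with all other genes by camera with a preset correlation between genes of 0.01, and again with a correlation estimated from the data, adjusted over the 28 lists of a comparison. Members were also counted with p adjusted over the list alone. The list score of a mouse is the mean over the list's genes minus the mean over all genes. Permuting that score over the mice of a sex or age class (100000 draws, two-sided), which was added after the data were examined, gave a further p per list.

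The test was tried on simulated data made from shuffled and from independent residuals, with 200 changed clones among the 16896. At a change of 0.2 array SD, 22% of the changed clones passed with shuffled and 42% with independent residuals in the maturation comparison, and 26% and 36% in 704-743 d against 169-194 d. At 0.5 array SD it was 100% with shuffled and 98% with independent residuals in both. For the oxidative phosphorylation list, a shift of -0.05 array SD put into shuffled residuals gave an adjusted p of 4.0e-08 with the preset correlation and 0.278 with the estimated one.

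Other settings, planned beforehand, were quantile normalization, median and MAD scaling, normal scores, filters on dim clones at 2 strengths, array weights, a trended and robust variance prior, fits without moderation, a block for each stretch of list numbers in the titles, a threshold of unadjusted p under 0.001, only the classes compared, either part of the youngest class alone, log2 age, ordinal age, each sex alone, all clones of a gene, only the genes brighter than the median, and each mouse left out in turn. One male of 704-743 d (replicate 2, 714 d) has a description that names another mouse, a male of 43 d; it was kept by its title and left out as an alternative. After the data were examined, further settings were added: subtracting from each spot the median deviation of the spots around it, in 4 window sizes (the layout of the filters is not in the sources used here; it was inferred from the clone-number distances at which residuals correlate), and taking the leading principal component of a mouse's other filter as a covariate. For gene lists this covariate was the mean of the scaled components of both filters. The 8 groups were also replaced by 100 regroupings of the mice. Figures were drawn with matplotlib 3.10.9.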

Results

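Skeletal muscle was sampled once per mouse, in 8 groups of 5 mice by sex and age class, and each mouse gave 1 array on each of the 2 filters. Ages run from 17 to 743 d. Values are z-scores of log-like intensity, so that a difference of 1 is 1 SD of the clones of an array, and the number of arrays limits the precision. Within a group, the median SD between mice was 0.141 array SD for a clone of filter A and 0.123 for a clone of filter B.

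Arrays of a filter resembled each other, with a median correlation across clones of 0.971 for filter A and 0.976 for filter B. The leading principal component took 43.6% of the variance between mice on filter A and 36.6% on filter B. Its values on the filters followed each other across the 40 mice (Pearson r = 0.962, Spearman rho = 0.965, permutation p = 1e-05 for each, the smallest that 100000 draws can give, 1 relation tested). Without the 2 mice farthest from the median r was 0.954, and within the 5 blocks of 8 mice by list number it lay between 0.978 and 0.994. On filter A the component averaged -8.44 ± 9.55 (SD, n = 10 mice) at 17-44 d, 4.77 ± 10.7 at 169-194 d, 5.32 ± 14.2 at 476-499 d and -1.65 ± 5.77 at 704-743 d. Within the youngest class it averaged -14.7 ± 1.41 in the 5 mice of 17-21 d and -2.19 ± 10.3 in the 5 of 33-44 d. Age class accounted for 24.0% of its variance on filter A and 25.5% on filter B.

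**Figure D1:**
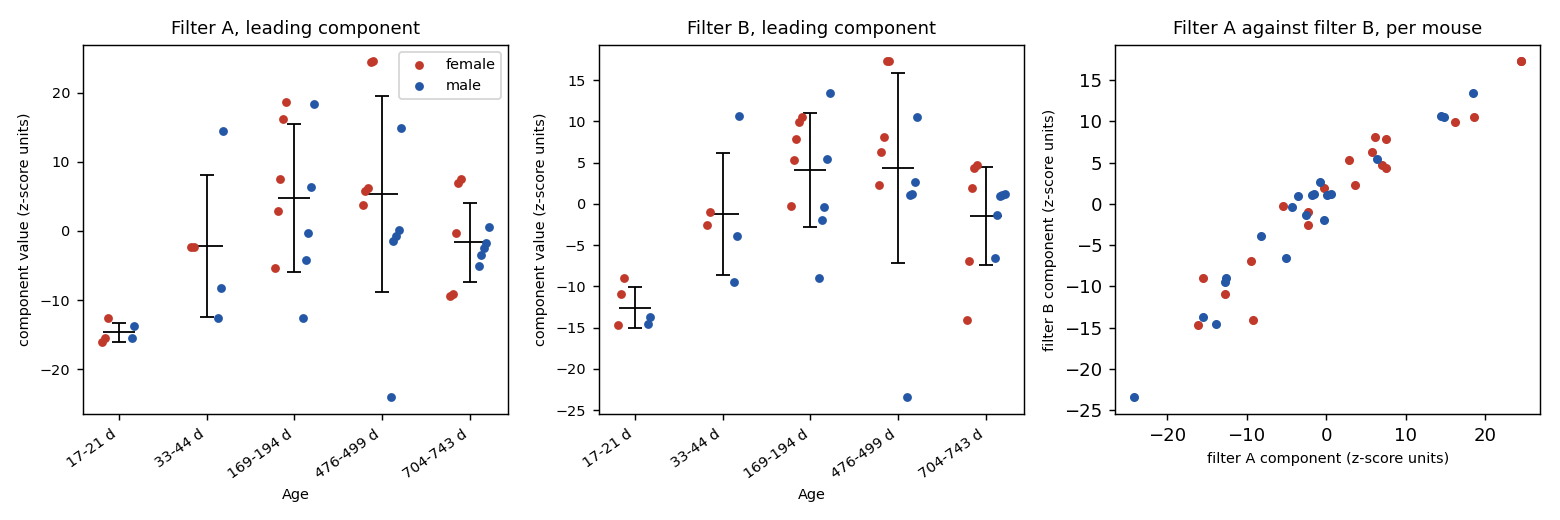
The first and second panels plot the leading component of each filter (z-score units) by age class, 1 point per mouse, female red and male blue, with bars for the mean and SD. The third panel plots filter B against filter A per mouse; on filter A the 5 mice of 17-21 d lie between -16.1 and -12.7.

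Transcripts that mark sex did not part the mice. Eif2s3y, a Y-linked translation initiation factor gene, averaged -0.382 ± 0.120 (SD, n = 20) in females and -0.428 ± 0.112 in males, and Uty, a Y-linked histone demethylase, -1.38 ± 0.0922 and -1.44 ± 0.217. Xist, the RNA that coats the inactive X chromosome, averaged -0.784 ± 0.146 in females and -0.863 ± 0.159 in males (adjusted p = 0.655 with limma). These clones stand at the 38.0, 5.17 and 17.8 percentiles of their filters. Why they did not part the mice was not tested, and the sex in the labels was taken as given.

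The first comparison asks how muscle of growing mice differs from that of young adults. Single clones of Col1a2, a chain of type I collagen, Col2a1, the collagen of cartilage, and Sparc, a collagen-binding glycoprotein, fell from 17-44 d to 169-194 d. H19, an imprinted noncoding RNA of the fetal period, also fell, as did Clca3a1, of the family of chloride channel accessory proteins. Cd24a, a surface glycoprotein of immature cells, rose. Col1a2 (clone 15060) went from 0.347 ± 0.364 (SD, n = 10) to -0.281 ± 0.121, a difference of -0.628 ± 0.0892 (SE, adjusted p = 0.000271). The differences were -0.588 ± 0.0870 for Col2a1 (adjusted p = 0.000283), -0.516 ± 0.0738 for Sparc (clone 6518, 0.000271), -0.301 ± 0.0452 for Clca3a1 (0.000283), -0.278 ± 0.0557 for H19 (clone 15040, 0.0277) and 0.269 ± 0.0498 for Cd24a (clone 13437, 0.0117). Clones 15082, 3338 and 14617, which have no symbol, also fell (-0.483, -0.220 and -0.244; adjusted p = 0.000283, 0.0161 and 0.0241). In each of these 9 clones all 10 mice of 169-194 d lay beyond the mean of 17-44 d. Col2a1 and Clca3a1 were named by the rule; the other 7 clones were chosen after their values were seen. Other clones of the same genes did not pass: Col1a2 clone 9008 differed by -0.017 (adjusted p = 0.788), Sparc clone 14923 by -0.051 (0.659), H19 clone 8789 by 0.076 (0.248) and Cd24a clone 8630 by 0.072 (0.236). Sparc has 4 clones and H19 has 7. Sparc clones 4342 and 2977 differed by -0.142 (adjusted p = 0.104) and 0.103 (0.120). H19 clone 15084 differed by -0.208 (0.0664), and the remaining H19 clones by -0.021 to 0.089. Cd24a clone 13437 is a dim clone, at the 12.6 percentile. The clone of Clca3a1, H19 clones 15040 and 15084 and clone 15082 lie near Col1a2 clone 15060 in a spot layout inferred from the data.

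**Figure D2:**
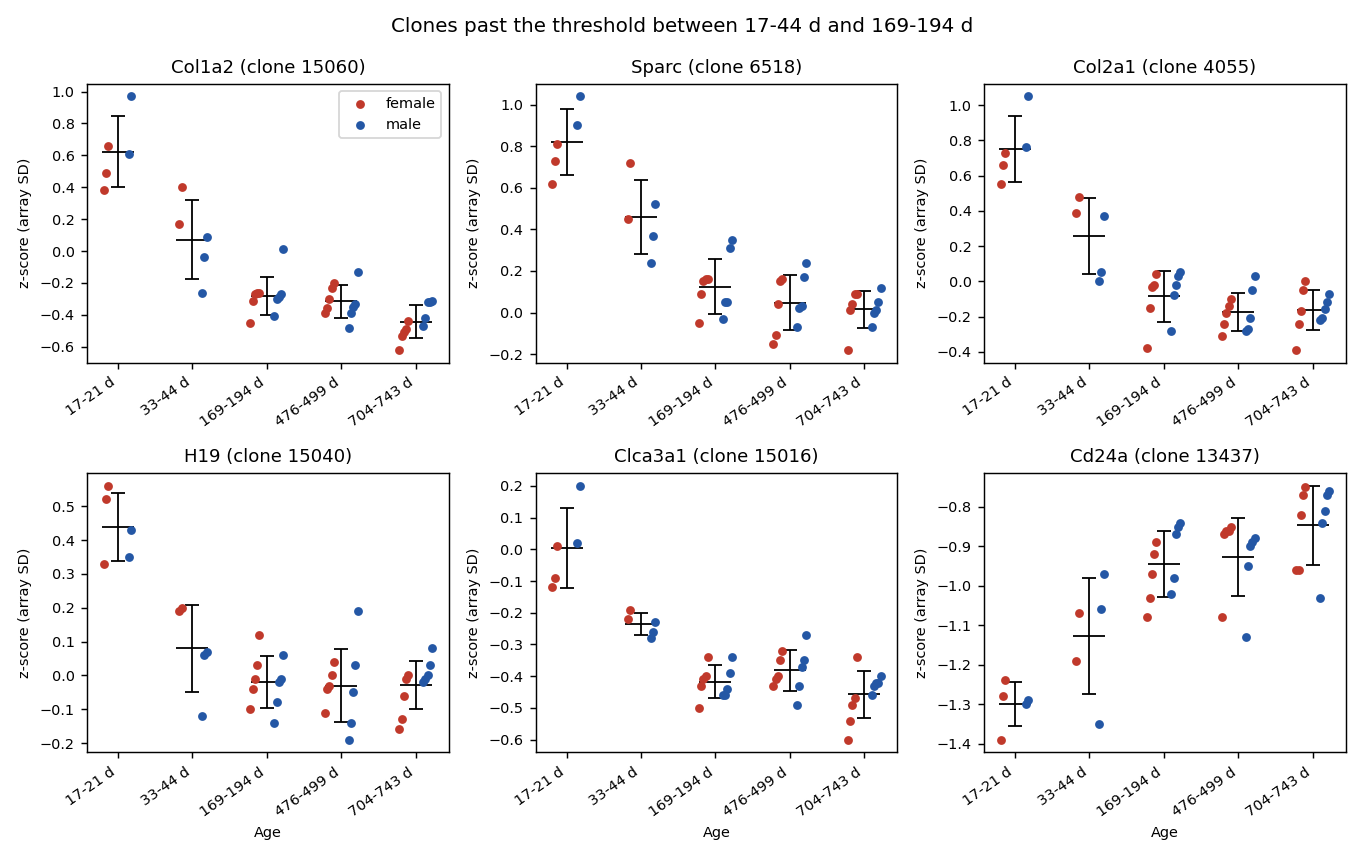
Z-score of 6 clones past the threshold, by age class with the youngest class split into 17-21 d and 33-44 d; points are mice (female red, male blue) and bars the mean and SD. Col1a2 averaged 0.622 at 17-21 d, 0.0720 at 33-44 d and -0.281 at 169-194 d, and Cd24a, the clone that rose, -1.30, -1.13 and -0.945.

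Beyond these, no gene named by the rule passed. The smallest p in each direction belonged to Macf1 (0.290), Stard4 (0.20), Ccdc192 (0.197), Ica1 (0.234) and Hip1 (0.156), and to Ypel5 (-0.146), Irf9 (-0.233) and Wdr36 (-0.279), each with an adjusted p of 0.0664; 10 of 10 mice of 169-194 d lay beyond the young mean, and 9 of 10 for Wdr36. No list passed camera. Of the 67 cytosolic ribosome genes, 56 were higher in value at 169-194 d (median 0.060, adjusted p = 0.159), and Actn3, Casq1 and Mylpf of the fast fibre list were all lower (median -0.190, 0.159; adjusted over the list alone, 2 fell). In the extracellular matrix list, 26 of its 41 genes were higher in value (median 0.053, adjusted p = 0.793), and adjusted over the list alone 2 rose and 0 fell. The median change over all genes was itself above 0, at 0.038 in females and 0.02 in males. In all, limma called 9 clones, 1 higher and 8 lower, while 6205 clones (36.7%) had an unadjusted p under 0.05 and 203 had one under 0.001. The count was 0 with only the mice of these 2 classes in the fit (adjusted p from 0.0585), 5 with the leading component of the other filter as a covariate and 8892 with array weights. It was 5390 without male 17-44 d replicate 5, 3364 without male 169-194 d replicate 1, 3283 without male 476-499 d replicate 5, 2664 without female 17-44 d replicate 4, 1978 without female 169-194 d replicate 5, 28 without male 169-194 d replicate 4 and 14 without female 704-743 d replicate 5. H19 was not past the threshold without any 1 of 10 mice: female 17-44 d replicates 1, 2 and 3, male 17-44 d replicates 3 and 4, female 169-194 d replicates 2, 3 and 4, and male 169-194 d replicates 2 and 5 (adjusted p up to 0.112). Clone 14617 lost its call without any of these but female 169-194 d replicate 2 (up to 0.0965), and clone 3338 without female 17-44 d replicate 1, male 17-44 d replicate 4 or male 169-194 d replicate 5 (up to 0.0618).

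The youngest class holds mice of 17-21 d and of 33-44 d, and fits with either part alone were planned. Col2a1 (-0.860 ± 0.0722, SE, adjusted p = 3.0e-09) and Clca3a1 (-0.439 ± 0.0425, 4.7e-08) fell from 17-21 d to 169-194 d, as did Bnip3, a mitophagy receptor on a clone at the 10.3 percentile (-0.404 ± 0.0609, 0.000336). Pigc, of glycosylphosphatidylinositol synthesis, rose (0.347 ± 0.0572, 0.00141), as did Rela, a subunit of NF-kB (0.249 ± 0.0431, 0.00260), Bmp1, a procollagen protease (0.392 ± 0.0759, 0.00631), and Fen1, a DNA repair nuclease (0.474 ± 0.0981, 0.00914). For each of these genes all 10 mice of 169-194 d lay beyond the mean of the 5 mice of 17-21 d; they were chosen after their values were seen. In all, 6409 clones passed, 2974 higher and 3435 lower, and 8623 (51.0%) had an unadjusted p under 0.05. Of the fast fibre list 0 rose, 2 fell and 1 did not pass; of the cytosolic ribosome 15 rose, 2 fell and 50 did not pass, and of oxidative phosphorylation 13, 4 and 44. Adjusted over the list alone the counts were 0 and 2, 12 and 2, and 11 and 3. Over all 7151 genes 1513 rose and 1183 fell. The share that rose in the ribosome and oxidative phosphorylation lists was near that of all genes, while the share that fell was smaller. No list passed camera (adjusted p = 0.156 for fast fibre, median -0.305; 0.222 for the cytosolic ribosome, median 0.0868). Between 33-44 d and 169-194 d 1 clone passed, lower, and 587 clones (3.47%) had an unadjusted p under 0.05. None of the genes just named passed there. Col2a1 differed by -0.372 (adjusted p = 0.117) and Clca3a1 by -0.186 (0.202). Bnip3 (-0.105), Pigc (0.081), Rela (0.077), Bmp1 (0.122) and Fen1 (0.183) had an adjusted p of 0.856. With the leading component of the other filter as a covariate, 9 of the 6409 clones remained, among them Col2a1 (-0.673, adjusted p = 1.7e-06), Clca3a1 (-0.429, 6.9e-06) and Bnip3 (-0.427, 0.00477). The calls of Pigc (0.232, adjusted p = 0.431), Rela (0.19, 0.424), Bmp1 (0.297, 0.998) and Fen1 (0.19, 1.00) ended with it. The clones of Clca3a1 and Bnip3 both lie near that of Col1a2 in the spot layout inferred from the data. They may therefore not be changes separate from that of Col1a2. Without male 17-44 d replicate 4 the count was 1356, without male replicate 3 of that class 2790 and without female replicate 2 3966.

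Within the youngest class, 33-44 d against 17-21 d, no gene passed. The values lowest in p were higher at 33-44 d for Polr2m (0.464 ± 0.0893, SE), Pdcl3 (0.328), Camta1 (0.344), Tbce, a tubulin folding cofactor (0.292), and Phf8, a histone demethylase (0.248). They were lower for Stard8 (-0.293), Mcl1, an antiapoptotic protein (-0.276), Bnip3 (-0.299), and the splicing factors Eftud2 (-0.273) and Prpf18 (-0.295). Each had an adjusted p of 0.170 with limma, in 5 of 5 mice. The clone of Bnip3 lies near that of Col1a2 in the inferred spot layout. The count was 0, against 3634 clones (21.5%) at an unadjusted p under 0.05; it was 134 with array weights and 14 with the block by list number. No list passed camera.

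The comparison of 704-743 d with 169-194 d asks what differs between old and young adult muscle. Genes of oxidative phosphorylation, the subunits of the respiratory chain and ATP synthase, fell as a list: 53 of 61 were lower in value at 704-743 d. The list's median was -0.057, against -0.014 over all genes (camera adjusted p = 6.5e-05), and the adjusted p was 0.893 with an estimated correlation. Examples are Atp5j, of ATP synthase (-0.16 ± 0.0528, SE), and the complex I subunits Ndufc1 (-0.155 ± 0.0619), Ndufb10 (-0.127 ± 0.0542) and Ndufa10 (-0.157 ± 0.0711), none of which passed singly (adjusted p = 0.750; 9, 8, 9 and 10 of 10 old mice below the mean of 169-194 d). The list's score was 0.254 ± 0.0393 (SD, n = 10) at 704-743 d and 0.308 ± 0.0543 at 169-194 d, lower in 9 of 10 old mice (permutation p = 0.0241, adjusted 0.430 over 28 lists). Over all clones, and adjusted over the list alone, 0 members passed. Over 17 other settings the list's median ranged from -0.0863 to -0.0365.

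No single gene passed between 169-194 d and 704-743 d. Wnt5b, a secreted ligand, had the smallest p among named genes with higher values (0.977 ± 0.226, SE), on a clone at the 1.43 percentile, followed by Riok3 (0.233), Rif1 (0.217), Aff4 (0.210) and Fnbp1l (0.146). Lower in value were Cav1, of caveolae (-0.199 ± 0.0550), Ttc39b (-0.235), Fh1, the fumarase of the TCA cycle (-0.170), and Lpgat1 (-0.240). For all of these the adjusted p was 0.750, and 9 or 10 of 10 old mice lay beyond the younger mean. The count with limma was 0, with 776 clones (4.59%) at an unadjusted p under 0.05 and 5 under 0.001.

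**Figure D3:**
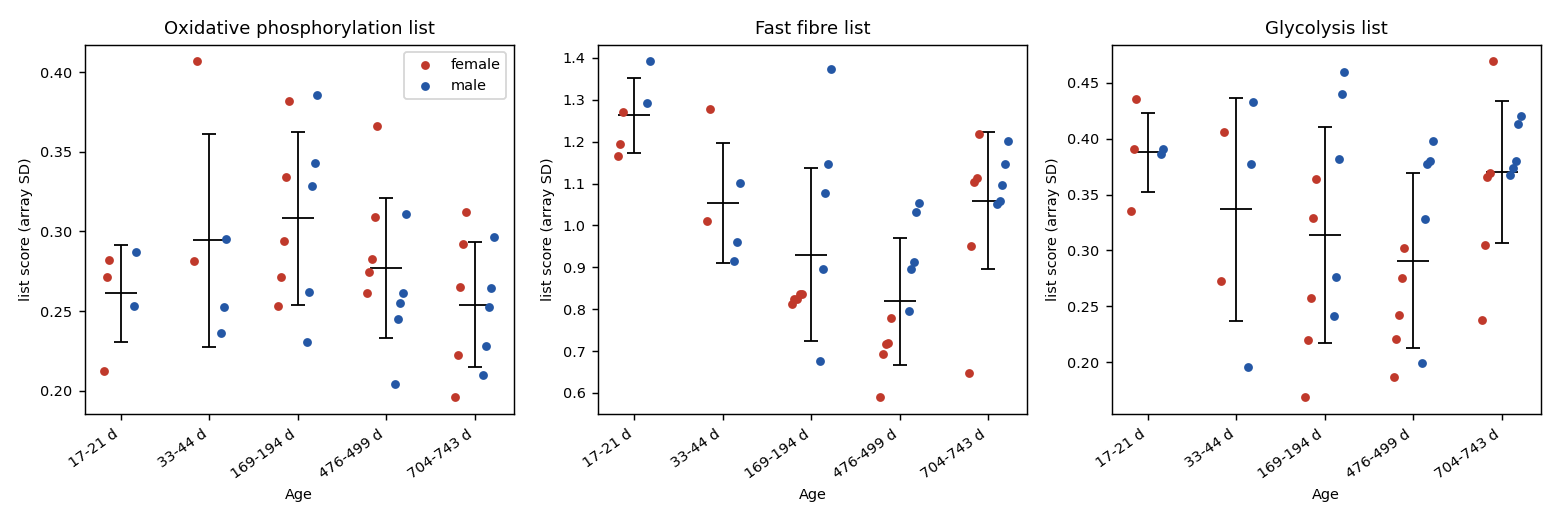
List score per mouse (mean of the list's genes minus the mean of all genes, array SD) by age class for oxidative phosphorylation, fast fibre and glycolysis; points are mice (female red, male blue), bars the mean and SD. Oxidative phosphorylation averaged 0.308 at 169-194 d, 0.277 at 476-499 d and 0.254 at 704-743 d.

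The step from 169-194 d to 476-499 d and the step from there to 704-743 d split this span. In the earlier step the oxidative phosphorylation list fell (median -0.020, 44 of 61 lower, 7 of 10 mice; adjusted p = 0.000327, and 0.436 with an estimated correlation), with Atp5o (-0.114), Ndufa12 (-0.142), Sdhb (-0.112) and Atp5md (-0.069) as its members lowest in p. The fast fibre list, genes of the contractile and calcium store apparatus of fast fibres, fell too: Actn3 (-0.161), Casq1 (-0.071) and Mylpf (-0.103), in 8 of 10 mice (adjusted p = 0.00606, and 0.243 with an estimated correlation). The developmental muscle list fell (median -0.052, 4 of 4 lower, 7 of 10 mice; adjusted p = 0.0182, and 0.184 with an estimated correlation), with Cdh2 (-0.055), Hmga2 (-0.049), Nes (-0.060) and Igf2bp1 (-0.027). Adjusted over the list alone, no member of these 3 lists passed (0 rose, 0 fell), and permuting their scores gave an adjusted p of 0.931 for each. Wnt5b (0.900), D13Ertd608e (0.155), Snx13 (0.078), Polr2j (-0.098), Med20 (-0.339) and Fth1, of ferritin (-0.159), had the smallest p of single genes, each with an adjusted p of 1 and in 8 to 10 of 10 mice. The limma count was 0, with 115 clones (0.681%) at an unadjusted p under 0.05. Leaving out 1 mouse ended the call of oxidative phosphorylation without male 169-194 d replicate 3 (adjusted p = 0.0646) or male 476-499 d replicate 5 (0.0839), of fast fibre without male 169-194 d replicate 4 (0.162), and of developmental muscle without any 1 of 7 mice. Those 7 were male 476-499 d replicate 5 (0.587), male 169-194 d replicates 3 (0.0642) and 4 (0.0771), female 169-194 d replicates 1 (0.0667) and 4 (0.0521), and female 476-499 d replicates 1 (0.0545) and 5 (0.0506). The median of oxidative phosphorylation was -0.0360, -0.0345 and -0.0107 without male 169-194 d replicates 1, 2 and 3 and -0.0340 without female 476-499 d replicate 5. That of fast fibre was -0.0400 without male 169-194 d replicate 4, and that of developmental muscle -0.0294 without male 476-499 d replicate 5. In other settings the adjusted p was above the threshold in 1 of 17 for oxidative phosphorylation (0.0652), 1 for fast fibre (0.0709) and 5 for developmental muscle (up to 0.174). The medians ranged over them from -0.0310 to -0.0120, from -0.110 to -0.0798 and from -0.0575 to -0.0241.

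In the later step, 704-743 d against 476-499 d, fast fibre and glycolysis genes rose as lists. The fast fibre list had a median of 0.168, higher in 9 of 10 mice (adjusted p = 0.00165, and 0.205 with an estimated correlation; permutation p = 0.00121, adjusted 0.0339). Of 18 glycolysis genes 12 were higher and 6 lower in value (median 0.0755, 9 of 10 mice; adjusted p = 0.0281, and 0.432 with an estimated correlation; permutation p = 0.00975, adjusted 0.118). Actn3, the alpha-actinin of fast fibres (0.409 ± 0.0860, SE), Casq1, the calcium-binding protein of the calcium store (0.116 ± 0.0582), and Mylpf, a fast myosin light chain (0.168 ± 0.0927), were higher in value in 9, 8 and 7 of 10 mice. Adjusted over the list alone, 1 of these 3 genes, Actn3, rose and 0 fell. The glycolysis genes lowest in p were Pkm (0.139), Gapdh (0.252), Aldoa (0.271) and Tpi1 (0.172), higher in 8 to 10 of 10 mice; adjusted over the list alone 0 passed. Over all clones none of these passed: the adjusted p was 0.525 for Actn3 and 0.566 for the others. Atf3, a stress-induced transcription factor (0.411 ± 0.101), and Casz1 (0.425 ± 0.106) were also higher in value, and Arl14ep (-0.132), Mllt6 (-0.145) and Rbak (-0.129) lower (adjusted p = 0.566; 8 to 10 of 10 mice). The clones of Actn3, Atf3 and Casz1 lie in 1 column of the spot layout inferred from the data. The limma count was 0, with 1214 clones (7.19%) at an unadjusted p under 0.05. It was 3 with array weights (Actn3, Atf3 and Casz1) and 1 without female 704-743 d replicate 5 (Actn3, 0.474, adjusted p = 0.00962). Other lists had higher scores in this step without passing: slow fibre (0.0879, permutation p = 0.0226, adjusted 0.127), sarcomere and excitation-contraction (0.0902, 0.0207, 0.127) and denervation and atrophy (0.0462, 0.0126, 0.118). Their camera adjusted p was 0.936, 0.290 and 0.437. The leading component of filter A averaged 5.32 and -1.65 in these classes, and with the mean component of both filters as a covariate the glycolysis median was 0.0435 (camera adjusted p = 0.0689). Over 17 other settings the median ranged from 0.0435 to 0.139 for glycolysis and from 0.131 to 0.201 for fast fibre. The glycolysis call ended in 4 of these settings (adjusted p up to 0.203) and without male 476-499 d replicates 3 (0.0632) or 5 (0.181), female 476-499 d replicate 5 (0.0787), or replicate 1 of female (0.0622) or male 704-743 d (0.0673).

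The slope on age was fitted over all mice, those of the youngest class included. Col1a2 fell along age (-0.0947 ± 0.0152 array SD per 100 d, SE, adjusted p = 0.00329), as did Sparc (-0.0763 ± 0.0127, 0.00329), Col2a1 (-0.0820 ± 0.0150, 0.0102) and Clca3a1 (-0.0383 ± 0.00753, 0.0282), and Cd24a rose (0.0443 ± 0.00753, 0.00348). For these 5 clones, the same as in maturation, all 10 mice of 704-743 d lay beyond the mean of 17-44 d; Col1a2, Sparc and Cd24a were chosen after their values were seen. From 169 d on the slopes of the 5 clones did not pass (adjusted p = 0.780 each): -0.0293 ± 0.00913 for Col1a2, -0.0198 ± 0.00990 for Sparc, -0.0153 ± 0.0104 for Col2a1, -0.00678 ± 0.00642 for Clca3a1 and 0.0178 ± 0.00820 for Cd24a. Not past the threshold (adjusted p = 0.875) were Hspb8, a small heat shock protein (0.0286), Rab2a (0.0329), Itch (0.0306), Prpf19 (0.0329) and Bmp1 (0.0328), and Ppox, of haem synthesis (-0.0296), Myl6 (-0.0408) and Mocos (-0.0213), in 8 to 10 of 10 old mice. The oxidative phosphorylation list passed as lower (median slope -0.00375, 38 of 61 lower, 7 of 10 old mice below the mean of 17-44 d; adjusted p = 0.0198, and 0.656 with an estimated correlation; permutation p = 0.10, adjusted 0.505), with Ndufc1 (-0.0229), Sdhb (-0.0209), Cox5b (-0.0210) and Ndufb6 (-0.0151) lowest in p and 0 members adjusted over the list alone. In 10 of 20 other settings its adjusted p was above the threshold (up to 0.731 with log2 age, where the list's median was 0.00486, above 0; lowest median -0.00670), as it was without any 1 of 13 mice (up to 0.287): female 17-44 d replicate 4, male 17-44 d replicate 5, female 169-194 d replicates 3 and 4, male 169-194 d replicates 3, 4 and 5, male 476-499 d replicate 5, female 704-743 d replicates 1, 2 and 3, and male 704-743 d replicates 2 and 4. The median slope was -0.00594 without female 17-44 d replicate 1, -0.00174 without replicate 4 of that group, -0.00248 without male 169-194 d replicate 3. It was -0.00244, -0.00162 and -0.00238 without female 704-743 d replicates 1, 2 and 3. Of the clones, 5 passed, 1 higher and 4 lower, and 646 (3.82%) had an unadjusted p under 0.05; the count was 98 with log2 age, and 0 in females alone and in males alone. Clca3a1 was not past the threshold with array weights (adjusted p = 0.158) or the block by list number (0.0576), after subtraction of spots in the window 1 1 1 (0.0782), nor without any 1 of the 5 females of 17-44 d, male 17-44 d replicate 3, or female 704-743 d replicates 1, 3 or 4 (adjusted p up to 0.0894).

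Over the 30 mice from 169 d, the slope of the oxidative phosphorylation list was lower than that of other genes (median -0.00998 per 100 d, 53 of 61 lower; adjusted p = 4.0e-05, and 0.876 with an estimated correlation; permutation p = 0.0126, adjusted 0.233). Its members lowest in p were Atp5j (-0.0285), Ndufc1 (-0.0287), Ndufs8 (-0.0187) and Ndufb10 (-0.0228), and adjusted over the list alone 0 passed. Single genes did not pass: Wnt5b (0.185 ± 0.0464, SE), Rif1 (0.0392), Aff4 (0.0379), Cav1 (-0.0369), Fh1 (-0.0311) and C9orf72 (-0.0242) had an adjusted p of 0.780, with 9 or 10 of 10 mice of 704-743 d beyond the mean of 169-194 d. The limma count was 0, with 644 clones (3.81%) at an unadjusted p under 0.05. With only the genes brighter than the median, the list's adjusted p was 0.0600; over 16 other settings its median ranged from -0.0158 to -0.00658.

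Between females and males, genes of fast fibres and of glycolysis were lower as lists in females. Of the fast fibre genes, Actn3 (-0.183 ± 0.0608, SE), Casq1 (-0.093) and Mylpf (-0.085) were lower in value in 12 or 13 of 20 females (list median -0.093, adjusted p = 0.0270, and 0.417 with an estimated correlation). Of the glycolysis genes 12 of 18 were lower (list median -0.0335, 13 of 20 females; adjusted p = 0.0307, and 0.417 with an estimated correlation), with Tpi1 (-0.142), Pgm1 (-0.095), Hk2 (-0.0605) and Aldoa (-0.149) lowest in p. Adjusted over the list alone, 2 fast fibre genes and 0 glycolysis genes fell, and permuting the list scores gave p = 0.0191 and 0.0318 (adjusted 0.174 each). Among single genes, none of which passed (adjusted p = 0.655), Amd2, of polyamine synthesis (-0.173 ± 0.0384, 19 of 20 females), Fbxl7 (-0.153), Nfe2l2, the antioxidant response factor (-0.169), Id2 (-0.187) and Ibtk (-0.192) were lower in value, and Gm36723 (0.0845), Coq8a, of coenzyme Q synthesis (0.139), Slc25a36 (0.135), Lcp1 (0.133) and Cyhr1 (0.0905) higher, in 14 to 19 of 20 females. The clones of Ibtk and Nfe2l2 are adjacent in the spot layout inferred from the data, and that of Fbxl7 lies near them. The 50 clones lowest in p held 33 pairs of neighbours, against at most 13 in random draws, so these genes may not be separate changes. The limma count was 0, with 985 clones (5.83%) at an unadjusted p under 0.05. The fast fibre call ended without male 169-194 d replicate 4 (adjusted p = 0.0625) or male 476-499 d replicate 2 (0.0691) and in 2 of 16 other settings (up to 0.178). The glycolysis call ended in 5 of 16 other settings (up to 0.178) and without any 1 of 8 mice (up to 0.0762): female 17-44 d replicates 1 and 5, male 17-44 d replicate 1, male 169-194 d replicates 2 and 4, female 476-499 d replicate 5, and male 476-499 d replicates 1 and 2. Over the other settings the median ranged from -0.101 to -0.0691 for fast fibre and from -0.0465 to -0.0177 for glycolysis. Sex accounted for 5.10% of the variance of the leading component on filter A and 3.91% on filter B. Both list scores tended to be lower in mice with a high value of that component.

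Restricted to the classes from 169 d, the difference between the sexes had more small p. Amd2 (-0.228 ± 0.0444, SE, adjusted p = 0.158, 15 of 15 females), Nfe2l2 (-0.233) and Id2 (-0.256) were lower in value in females, and Vkorc1, of the vitamin K cycle (0.191), Fdft1, of cholesterol synthesis (0.207), and Pex6, of peroxisomes (0.165), higher (adjusted p = 0.263; 13 or 14 of 15 females). The fast fibre list fell in females against males: Actn3 (-0.251), Casq1 (-0.129) and Mylpf (-0.149) gave a median of -0.149, in 12 of 15 females (adjusted p = 0.0203, and 0.418 with an estimated correlation; permutation p = 0.00173, adjusted 0.0400). The glycolysis list fell as well (median -0.042, 12 of 18 lower, 11 of 15 females; adjusted p = 0.0262, and 0.418 with an estimated correlation; permutation p = 0.00921, adjusted 0.0860). Adjusted over the list alone 2 fast fibre genes fell, and 4 of glycolysis: Hk2, the hexokinase of muscle (-0.106, 15 of 15 females), Tpi1 (-0.199), Pgm1 (-0.129) and Aldoa (-0.223). Among the 50 clones lowest in p, 40 pairs were neighbours in the spot layout inferred from the data, against at most 13 in random draws. The limma count was 0, with 2582 clones (15.3%) at an unadjusted p under 0.05 and 59 under 0.001. Without male 169-194 d replicate 3 it was 9, all lower in females, among them Amd2 (-0.249, adjusted p = 0.0178), Nfe2l2 (-0.258, 0.0329) and Id2 (-0.291, 0.0329). The fast fibre call ended without male 476-499 d replicate 2 (adjusted p = 0.0546) and in 1 of 16 other settings (0.103). The glycolysis call ended without that mouse (0.0644), male 169-194 d replicate 2 (0.0523), male 476-499 d replicate 1 (0.0502) or female 476-499 d replicate 5 (0.0531), and in 4 of 16 other settings (up to 0.103). Over these the median ranged from -0.171 to -0.126 for fast fibre and from -0.0733 to -0.0208 for glycolysis. Among the mice from 169 d, the leading component of filter A was on average higher in females than in males. Mice high on it tended to have low fast fibre and glycolysis scores. The differences of these lists may therefore follow that component as well as sex.

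The sexes were also compared in their slope on age and in maturation. For the slope no gene passed: Znrf3 (0.0303 ± 0.00942 per 100 d, SE), Smg6 (0.0251) and Ankrd12 (0.0266) had higher values in females, and Tubg1, a gamma-tubulin (-0.0353), Bckdha (-0.0414) and Bik (-0.0584) lower ones, each with an adjusted p of 1.00. With limma 0 clones passed, and 200 clones (1.18%) had an unadjusted p under 0.05; no list passed (smallest adjusted p 0.506 with an estimated correlation). In maturation, 3 lists of muscle genes differed between the sexes with the preset correlation, but with an estimated one the adjusted p of each was 0.222. From 17-44 d to 169-194 d the fast fibre list changed by a median of -0.290 in females and -0.090 in males (difference -0.214, adjusted p = 0.0143), glycolysis by -0.045 and 0.021 (-0.063, 0.0143), and the sarcomere and excitation-contraction list by -0.094 and 0.062 (-0.102, 0.0232). The mean change of the latter in males was -0.00156, of the other sign than the median. Permuting the list scores gave an adjusted p of 0.818, 0.839 and 0.756. No member passed over all clones or adjusted over the list alone (0). Members lowest in p were Mylpf (-0.340) of the fast fibre list, Hk2 (-0.172) of glycolysis, and Tpm2 (-0.264) and Tpm1 (-0.294), the tropomyosins, and Actn2 (-0.416) of the sarcomere list. Single genes with the smallest p were Dcbld1 (0.502), Btbd10 (0.310) and Ttc26 (0.206), and Wdr36 (-0.414), Kitl (-0.296) and Myl6 (-0.444), at an adjusted p of 0.995. The limma count was 0, with 213 clones (1.26%) at an unadjusted p under 0.05. All 3 list calls ended without female 17-44 d replicate 4 or male 169-194 d replicate 4. Further, the fast fibre call ended without male 17-44 d replicates 1 or 2, the glycolysis call without male 17-44 d replicate 5, female 169-194 d replicate 4 or male 169-194 d replicate 2, and the sarcomere call without the latter pair, male 17-44 d replicates 2 or 4 or female 169-194 d replicate 1 (adjusted p up to 0.0786, 0.0786 and 0.106). The difference was -0.344 for fast fibre without male 169-194 d replicate 3, and -0.110 and -0.0983 for glycolysis without replicate 5 of female 17-44 d or female 169-194 d. Of 16 other settings, 3 ended the fast fibre call (up to 0.0720), 1 the glycolysis call (0.182) and 2 the sarcomere call (up to 0.105). The differences ranged over them from -0.258 to -0.129, from -0.112 to -0.0470 and from -0.264 to -0.0721.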

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

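The screen for mice apart from their group and the comparison of the sexes in maturation were planned, while the tests of explanations in this part, regroupings of the mice included, were written down after the results were seen.

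Of 136 groups of 5 mice tested over 17 measures, 11 hold a mouse that stands apart from the other 4; chance gives this in about 1 in 20 groups, or 6.8 of 136. The leading component stood apart in male 17-44 d replicate 5 (14.5 on filter A) and male 476-499 d replicate 5 (-23.5 on filter B). The median correlation with the other arrays stood apart in female 704-743 d replicate 5 (0.962), male 169-194 d replicate 3 (0.964) and male 476-499 d replicate 5 (0.941) on filter A, and in the latter also on filter B (0.944). Single clones stood apart for Cd24a in female 476-499 d replicate 5 (-1.08) and male 476-499 d replicate 5 (-1.13), for Col1a2 in female 169-194 d replicate 5 (-0.45), and for clone 15082 in female 17-44 d replicate 5 (-0.13). The glycolysis score of male 17-44 d replicate 5 was 0.196.

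Genes of glycolysis, fast fibres and the sarcomere differed between the sexes in their change from 17-44 d to 169-194 d with the preset correlation, but not with an estimated one (adjusted p = 0.222 each) nor by permuting the list scores (adjusted p = 0.839, 0.818 and 0.756). The female change minus the male change had a median of -0.063 for glycolysis, -0.214 for fast fibre and -0.102 for sarcomere and excitation-contraction.

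The first pattern is the set of 9 clones, with Col1a2, Sparc, Col2a1, Clca3a1, H19 and Cd24a, that differed between 17-44 d and 169-194 d. Of 100 regroupings, the real one included, 4 gave as many, a share under 0.05 that is not adjusted for the other comparisons regrouped. The 3 others with calls each gave over 5 times the count (highest 2125), which points to a structure of the samples. Chance is therefore not firmly excluded. Against a background shared by a region of spots, whose positions are inferred from clone order, 8 of the 9 clones stayed past the threshold after subtraction of the spots around them (clone 3338 went from -0.220 ± 0.0418, SE, to -0.132 ± 0.0382, adjusted p = 0.0533), but neighbours still clustered among the 50 clones lowest in p (27 pairs before, 29 after, at most 13 in random draws), so that the subtraction does not exclude such a background. Signal shared with the spots around cannot be told apart from a change of the clones' own. Of the 9, 3 (Col1a2, Sparc and Col2a1) changed by over 2 SE more than each of 74 spots around them. But these are the largest changes of the 9, which selection favours. The residuals of Col1a2 and the nearby clone 15082 (-0.483) correlated at 0.863. Clca3a1 (-0.301) and H19 (-0.278) changed less than Col1a2 (-0.628), a spot near both. Their residuals correlated with those of Col1a2 at 0.742 and 0.480. Against the array-wide component, 5 clones (Col1a2, Sparc, Col2a1, Clca3a1 and 15082) stayed past the threshold with the other filter's component as a covariate (adjusted p up to 0.0293). The other 4 did not, as the difference shrank for H19 (-0.278 ± 0.0557 to -0.175 ± 0.0498), Cd24a (0.269 ± 0.0498 to 0.20 ± 0.0496) and 3338 (to -0.163 ± 0.0413) and the error grew for 14617 (-0.244 ± 0.0481 to -0.248 ± 0.0535). For these 4 the component stays open, because its mean on filter A differed between the classes compared (-8.44 ± 9.55, SD, at 17-44 d and 4.77 ± 10.7 at 169-194 d). The age of the mice stays open as an untested explanation.

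The second pattern is the 6409 clones between 17-21 d and 169-194 d. No other of 100 choices of 5 young mice gave as many (1 with the real one, highest other 5927), though all 99 others gave calls. These choices exchange mice only within the youngest class, so they cannot test chance for a difference from 169-194 d. They show only that the mice of 17-21 d gave more calls than any other choice from their class. Choices that hold 4 of the 5 mice of 17-21 d called a median of 4071.5 clones and those with 2 of them a median of 5. After subtraction of the spots around, 6313 clones were past the threshold, 4427 of them among the 6409, but neighbours still clustered among the 50 lowest in p (27 pairs before, 35 after), so that a background shared by a region is not excluded. With the other filter's leading component as a covariate 9 clones were past it, and across clones, which are not independent replicates, the differences and the component's loadings correlated at 0.953, so that an array-wide component may carry most of the pattern. Whether that component is technical or follows age was not tested, and age stays open. The 4 age classes, with the youngest taken whole, account for 24.0% of it on filter A. There it averaged -14.7 ± 1.41 (SD) at 17-21 d, -2.19 ± 10.3 at 33-44 d and 4.77 ± 10.7 at 169-194 d.

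The third pattern is the lower oxidative phosphorylation list at 704-743 d than at 169-194 d. Chance cannot be excluded: 8 of 100 regroupings gave a list median as far from that of all genes as the real -0.043 (highest other 0.056). After subtraction of the spots around, the list's median went from -0.057 to -0.046, with a camera adjusted p of 0.000324 with the preset correlation. The list's genes were neighbours of each other about as often as random genes (8 pairs, and 438 of 1000 draws had as many). A background shared by a region is still not excluded, since neighbours stayed clustered among the 50 clones lowest in p (23 pairs before, 15 after, at most 13 in random draws). With the mean leading component of both filters as a covariate, the list's median was -0.0422 and its camera adjusted p was 1.3e-05 with the preset correlation. That setting takes the genes as nearly independent, so this p does not decide on the array-wide component. With an estimated correlation the camera adjusted p was 0.893 before these corrections and 0.812 and 0.253 after them, so there was no call to lose. Age stays open as untested.

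For the comparisons with a count of 0, all 100 regroupings give as many by construction, so they say nothing about chance. The highest other counts were those of 704-743 d against 169-194 d (1), 476-499 d against 169-194 d (558), 704-743 d against 476-499 d (1), the slope from 169 d (0), sex (53), sex from 169 d (1), the sexes' slopes (2892), their maturation (0) and the parts of the youngest class (1721). Single regroupings with 558, 53, 2892 and 1721 clones point to a structure of the samples. On filter A their contrasts correlated with the leading component at 0.406, 0.242, 0.368 and 0.670 (0, 13, 0 and 1 of 99 regroupings were higher), and that of the 2125 clones above at 0.385 (2 higher). The block of mice by list number, which accounts for 52.2% of the second component on filter A and 40.1% on filter B, accounted for 15.0%, 10.0%, 9.44% and 83.3% of these contrasts (23, 41, 51 and 17 higher). For the slope on age over all mice, with 5 clones against a highest other of 0, only the real grouping gave as many (1 of 100). This share is not adjusted for the other comparisons regrouped.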

How the results depend on the processing

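Subtracting the spots around a spot and taking the other filter's leading component as a covariate were chosen after the data were seen; the other settings were planned. In every setting run the limma count stayed at 0 for the sexes' maturation, as it did, apart from the threshold of unadjusted p under 0.001, for ageing, early adult ageing, the adult age trend, sex and age by sex. The median of oxidative phosphorylation in the age trend turned from -0.00375 per 100 d to 0.00486 with log2 of age, where its call was lost (adjusted p = 0.731). Over the 149 results of named genes, other settings kept direction and call 2196 times, gained a call 52 times, lost one 45 times and reversed 3. Most of these results were not past the threshold, and staying so counts as kept. Only the 9 clones of maturation and the 5 of the age trend had a call to lose, so the total of kept results does not measure how stable the calls are. The signal over background of a spot, which limits dim clones such as those of Wnt5b and Cd24a, is not known. The fit without moderation was not run for lists, and array weights did not fully converge in some fits. No scaling moved the median of all clones by 0.1. The cause of a change was not tested, and the remarks in brackets below only say how a setting differed.

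The 9 clones of maturation, 169-194 d minus 17-44 d, became 22 with median and MAD scaling, 1366 without the clones dimmer than the median (fewer clones tested), 8892 with array weights, 14 with the replicate block, 203 at unadjusted p under 0.001, 0 with only the 2 classes compared (fewer mice), 1 with the youngest class only 33-44 d and 6409 with it only 17-21 d. With neighbouring spots subtracted they were 20, with window 1 1 0 437, with window 3 3 1 25, and with the leading component as covariate 5. Leaving out 1 mouse gave 6 to 5390. Quantile normalization ended the calls of Cd24a, H19 and clone 14617 (adjusted p = 0.0530 each), normal scores those of H19 (0.0640) and 14617 (0.0771), and the window 1 1 1 those of Cd24a, H19 and 3338 (0.0553 each).

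The 5 clones of the age trend became 2 without the clones dimmer than the median, 12 at unadjusted p under 0.001, 98 with log2 of age, 0 in females only and 0 in males only (fewer mice each). The 0 of late ageing, 704-743 d minus 476-499 d, became 3 with array weights, 16 at unadjusted p under 0.001, and 0 to 1 without 1 mouse; the 0 of adult sex became 59 at unadjusted p under 0.001, and 0 to 9 without 1 mouse. Within the youngest class the 0 became 134 with array weights, 14 with the replicate block and 52 at unadjusted p under 0.001. At that threshold ageing gave 5, early adult ageing 1, the adult age trend 3, sex 6, age by sex 1, and the gene lists 9 in place of 15; with window 1 1 0 the lists gave 7, and without 1 mouse 10 to 20.

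The oxidative phosphorylation list in ageing and the fast fibre list in late ageing kept their calls in all 17 settings and 40 fits without 1 mouse (adjusted p up to 0.0360 and 0.0393), all with the preset correlation. With an estimated correlation both calls were lost (adjusted p = 0.893 and 0.205). The reversals were all below any threshold: Igf2bp1 in early adult ageing (-0.027) was 0.00664 with median and MAD scaling, 0.00528 with array weights and -0.0705 to 0.0558 without 1 mouse, and Smg6 in age by sex (0.0251) was -0.000998 with window 1 1 0.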

Other observations

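The gene lists below were planned, while the permutation of list scores and the tests of spot position were chosen after the data were seen. In maturation, the denervation and atrophy list, of genes that rise in denervated or wasting muscle, fell by the permutation of list scores from 17-44 d to 169-194 d (score difference -0.0814, p = 0.00251, adjusted 0.0414 over 28 lists), and the developmental muscle list rose (0.0748, p = 0.00296, adjusted 0.0414). Neither passed camera (adjusted p = 0.62 and 0.793, and 0.940 and 0.947 with an estimated correlation). The leading component of filter A also differed between these classes (-8.44 ± 9.55, SD, at 17-44 d and 4.77 ± 10.7 at 169-194 d). Mice high on it tended to have a low denervation score and a high developmental muscle score. Permuting the mice cannot separate the lists from that component. Adjusted over the list alone, 1 of 8 denervation genes rose, Mt1, a metallothionein (0.213), and 2 fell, Fbxo30, a ubiquitin ligase subunit (-0.246), and Bnip3, the mitophagy receptor (-0.242, on a clone at the 10.3 percentile that lies near that of Col1a2 in the inferred spot layout). Of 4 developmental genes 2 rose in the same way, Igf2bp1, an RNA-binding protein of fetal tissues (0.297), and Hmga2, a chromatin protein (0.102), while other clones of Hmga2 were lower in value (-0.104 and -0.091). In sex from 169 d, the sarcomere and excitation-contraction list was lower in females by the permutation of list scores (-0.0946, p = 0.00286, adjusted 0.0400; camera 0.0774, and 0.430 with an estimated correlation), with 2 of 9 genes lower adjusted over the list alone. This score, too, tended to be low in mice high on the leading component, which was on average higher in these females than in the males.

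Lists of other cell types did not pass in maturation or in 704-743 d against 169-194 d. In maturation the medians below stand beside a median over all genes of 0.038 in females and 0.02 in males. For adipocyte genes the medians were -0.0265 and -0.0135 (adjusted p = 0.948 and 0.988), for erythroid and blood 0.027 and -0.020 (0.948 and 0.867), nerve and Schwann cell 0.0935 and -0.0385 (0.948 and 0.827), endothelial cell -0.078 and 0.0125 (0.654 and 0.948), skin and epithelium 0.0445 and -0.024 (0.948 and 0.894), and immune and antigen presentation 0.003 and -0.016 (0.992 and 0.701). For muscle and metabolism the medians were 0.048 and -0.014 in slow fibre (0.948 and 0.827), 0.053 and -0.0225 in TCA cycle and fatty acid oxidation (0.948 and 0.894), and 0.073 and -0.047 in the insulin-like growth factor axis (0.919 and 0.656). Protein synthesis and turnover gave 0.0285 and -0.033 for the mitochondrial ribosome (0.958 and 0.683), 0.049 and -0.0145 for the proteasome (0.919 and 0.867), 0.040 and -0.017 for the lysosome (0.919 and 0.931), and 0.0345 and 0.0025 for heat shock and chaperones (0.948 and 0.851). The cytosolic ribosome had a median of -0.028 and the extracellular matrix of -0.031 in the second comparison (0.159 and 0.683). Growth and stress lists gave 0.022 and -0.025 for imprinted growth genes (0.958 and 0.895), 0.041 and -0.010 for the cell cycle (0.958 and 0.895), 0.0725 and -0.005 for antioxidant genes (0.948 and 0.701), -0.0175 and -0.007 for p53 and senescence (0.948 and 0.902), 0.0285 and 0.0075 for the circadian clock (0.948 and 0.988), 0.10 and -0.0295 for X inactivation and escape (0.948 and 0.988) and 0.060 and -0.010 for hormone-responsive genes (0.919 and 0.894). In maturation the median and the mean differed in sign for slow fibre (mean -0.0833), adipocyte (0.0256) and p53 and senescence (0.0161), as they did in the second comparison for slow fibre (0.107), heat shock and chaperones (-0.00313) and the circadian clock (-0.005). For imprinted growth genes and erythroid and blood in maturation, the median was above 0 and the test leaned lower.

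Clones at certain distances in clone order varied together; the layout of the filters is not in the sources used here, and a grid of spots was inferred from these distances. After removal of group means and the 3 leading components, the residuals of clones 22 numbers apart correlated at 0.441 on filter A and 0.450 on filter B, those 528 apart at 0.402 and 0.396 and adjacent ones at 0.396 and 0.386, the highest of 2000 distances (median 0.0728 and 0.0480). Among the 50 clones with the smallest p, pairs of neighbours on that grid numbered 27 in maturation, 23 in 704-743 d against 169-194 d, 21 in the later step, 24 in the age trend, 14 in it from 169 d, 22 within the youngest class, 33 in sex and 40 in sex from 169 d. For comparison, 1000 random draws of 50 clones had a median of 4 and at most 13. They numbered 13 in the earlier step and in the sexes' maturation (1 draw had as many) and 10 in the sexes' slopes (15 draws). After subtraction of the spots around, the pairs were 29 in maturation, 24 in the age trend and within the youngest class, 25 in sex, 32 in sex from 169 d and 4 to 15 in the others. The correlations at these distances were then 0.221 and 0.248, 0.148 and 0.162, and 0.132 and 0.121. Actn3, Atf3 and Casz1, higher in value at 704-743 d than at 476-499 d, lie in 1 column of that inferred grid, with residual correlations of 0.894 to 0.966. Ibtk, Nfe2l2 and Tpm1, of the sarcomere list, lower in value in females (-0.192, -0.169 and -0.196; adjusted p = 0.655), lie in another, with 0.860 to 0.941. After subtraction of the spots around, Actn3 differed by 0.372 ± 0.0856 (SE, adjusted p = 0.433). Pairs of clones of 1 gene had a median residual correlation of 0.0611 over 3453 pairs, against -0.00479 for random pairs, and 0.322 where both were among the brightest (209 pairs).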
